A study of Mus musculus with 6 samples.

How the data were processed

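The Drop-seq values were counts of transcripts per gene and barcode, made by the authors before the files were deposited. The bulk values were read counts per gene with HTSeq's summary lines, also made by the authors before deposition. Per the submitters' processing notes STAR and HTSeq were used, with no versions and no statement of which step each served. The genome build, the gene annotation and the strand setting were not given in the sources used here. That the Drop-seq values are UMI counts follows from Drop-seq, named in the labels' protocols, and was not stated in the files. Per the labels' protocols the bulk libraries were made with a TruSeq stranded mRNA kit, from 500 ng of total RNA of glomeruli lysate (whole) and 95 ng of total RNA of sorted, fixed cells (dissociated). Coordinates are GENCODE GRCm38 gene positions and may differ from the authors' annotation. Near-identical copies such as Hspa1a and Hspa1b, and overlapping or antisense genes, cannot be told apart with certainty in these counts.

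The 4 Drop-seq tables held 15465 barcodes. Replicates 1 to 4 kept 4099, 4017, 2809 and 3068 cells, with medians of 816, 1156, 907 and 1003.5 UMIs. The bulk tables assigned 9.68% (whole) and 6.14% (dissociated) of reads to no gene, 3.77% and 3.87% to more than 1 gene, and 9.47% and 14.7% to more than 1 position. Mitochondrially encoded genes held 1.56% and 1.93% of bulk counts, and the 10 most abundant genes 5.08% and 7.98%. No pair of Drop-seq tables was a duplicate (chi-square per degree of freedom 4.41 to 15.6), and 7 barcodes stood in all 4 libraries, 0 of them among the kept cells.

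Cells with at least 300 detected genes and at most 20% mitochondrial UMIs were kept. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 gave 13 clusters (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9). The 11 held-out lists (282 genes, 276 with a UMI, 9 of them in 2 lists) were left out of the clustering, and no marker gene stood in them. Each cluster was scored on the 8 marker lists. Among lists scoring within 0.15 of the highest, the name went to the one with most markers among the cluster's 10 leading genes. Ties went to the higher score. Mesangial and smooth muscle and renin markers were joined as mural-like after the clusters were seen, because 1 cluster carried both. Cluster 6, named tubular-like, scored 0.583 on tubular and 0.576 on parietal epithelial markers. Scrublet (expected share 6%) marked 14 of 13993 cells, under the 0.5% taken as a sign that it had worked, so no doublets were removed and the alternative without removal was identical.

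UMIs were summed per library and cell type, for types with at least 20 cells in at least 3 libraries, and tested with edgeR 4.0.16 (quasi-likelihood test, TMM, library as a block, Benjamini-Hochberg, threshold 0.05) on R 4.3.3, each type against the mean of the other 4. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated one, adjusted over all lists and types. DESeq2 1.42.0 was an alternative. Endothelial-like cells were clustered again on 1000 variable genes at resolution 0.5. Bulk libraries were compared as TMM-scaled CPM (factor 0.810) with a prior count of 2 for genes with at least 100 counts, and list medians were placed among those of 10000 random lists matched in 20 expression bins. Drop-seq libraries were summed over all barcodes and correlated with each bulk library over genes with at least 100 bulk counts and 10 UMIs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0 were used.

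Groups, lists, tests, thresholds and the alternatives were chosen before the data were examined, apart from those named here as chosen later. Genes were named by rule: held-out genes past the threshold and in the same direction in every library, up to 20 rises and 5 falls per type, 8 per endothelial subcluster and direction, and in bulk the 10 largest rises and falls and 4 members per list. Genes outside this rule (single members that moved against their list, Fos, Sgpl1, Osgep and Ier3 among them, and in the subclusters Aqp1, Ehd4, Cav1 and Dll4) were chosen after their values were seen. Also chosen later were the mural union, the split of tubular markers, 2 alternatives for doublets, and the runs without 1 library for lists and for the correlation with bulk.

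The fit was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 86% and 97% of them in podocyte-like, 61% and 92% in endothelial-like, 37% and 78% in mural-like, 46% and 80% in parietal epithelial-like and 77% and 96% in tubular-like cells. There were 3 to 13 false calls among the unchanged of 7559 genes. For the subclusters it recovered 83% and 99%, with 10 false calls. Apart from the changed genes, the simulated types and libraries had equal profiles. In the real data more genes passed, from 761 higher and 319 lower in parietal epithelial-like to 2042 and 1961 in tubular-like cells. False calls under such broad differences were not tested. In simulated bulk data a list raised 2-fold had a median of 0.85, a lowered one -1.09 and an unchanged one 0.08.

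The alternatives were other cell filters, resolutions, clustering with the held-out genes, clustering and testing on separate UMIs, other scalings and tests, no low-count filter, no library block, each type against all other cells summed, single libraries left out, and for bulk other scalings, prior counts and count limits. Immune-like cells were too few for a test. Reads, splicing and sequence variants were not analysed here. Results of some single genes are not reported here.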

Results

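Gene expression was measured in glomeruli, the capillary tufts in which the kidney filters blood, from 8-week-old male mice of the outbred CD1 stock. 4 Drop-seq libraries (replicates 1 to 4) came from dissociated glomerular cells fixed in 80% methanol. Drop-seq captures single cells in droplets with barcoded beads and counts each captured transcript once through a unique molecular identifier (UMI). 1 bulk RNA-seq library came from whole live glomeruli (500 ng of RNA) and 1 from dissociated, methanol-fixed and sorted glomerular cells (95 ng). The labels did not say whether the libraries came from separate animals, so p-values measured only the spread between these libraries, which may be technical. The Drop-seq tables held 4484108 UMIs in 4623 barcodes (replicate 1), 6411775 in 4429 (replicate 2), 3528543 in 3077 (replicate 3) and 4133132 in 3336 (replicate 4). After 888 barcodes with fewer than 300 detected genes and 584 with more than 20% mitochondrial UMIs were left out, 13993 of 15465 barcodes remained, with a median of 965 UMIs and 638 genes. The bulk libraries held 28407317 reads on genes (whole) and 24555632 (dissociated).

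The series was described as an atlas, and the first question was which cell types the dissociated glomeruli held. Podocyte-like cells, the epithelial cells whose foot processes cover the capillaries, made up 74.3% ± 5.29 (SD, n = 4 libraries) of the kept cells, and endothelial-like cells 13.9% ± 6.39. Tubular-like cells accounted for 6.67% ± 2.86 and parietal epithelial-like cells, which line Bowman's capsule, for 2.38% ± 0.431. The tubular-like share depends on the mitochondrial limit: clustered without it, 542 of the 584 barcodes over the limit were tubular-like. Mural-like cells, with transcripts of mesangial, smooth muscle and renin-producing cells, made up 2.37% ± 1.12. The endothelial-like share ranged from 7.05% in replicate 2 to 22.2% in replicate 3, and the tubular-like share reached 10.9% in replicate 2. Immune-like cells were 0.386% ± 0.133 (52 cells), too few for a comparison of genes. No cluster was named red blood cell-like, but the endothelial-like cells held 1473 hemoglobin UMIs, 1151 of them in 1 barcode, so single red blood cells among the kept barcodes are not ruled out.

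**Figure D1:**
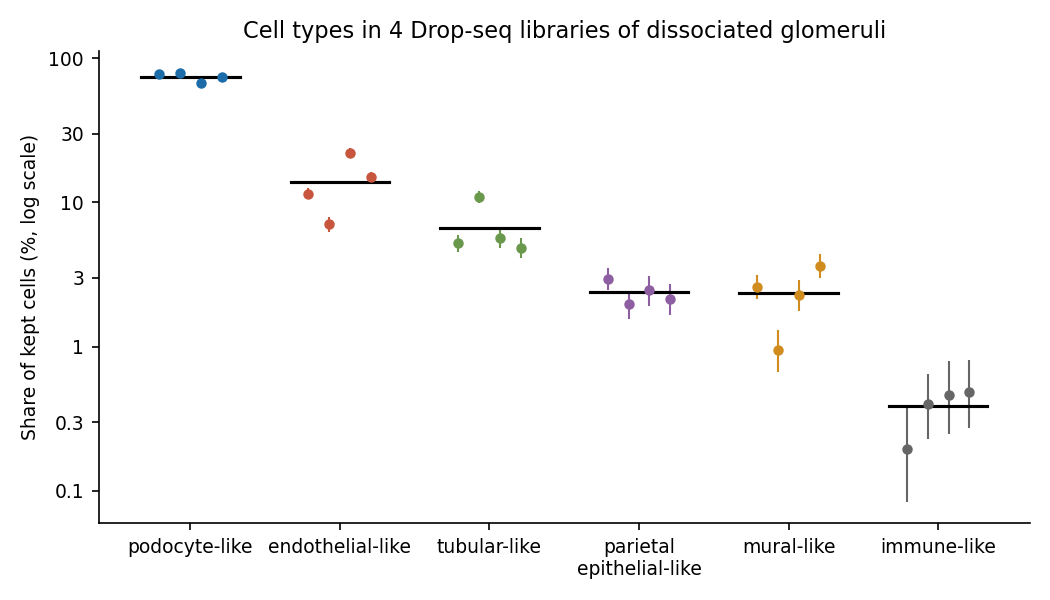
Share of kept cells (%, log axis) by cell type, 1 point per Drop-seq library with its exact 95% binomial interval and a black line at the mean of 4 libraries. Podocyte-like cells lie between 67.0% and 78.7% in every library, and mural-like cells between 0.946% and 3.65%.

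Each name rested on its marker genes. Levels are in CPM, the UMIs of a gene per 1000000 UMIs of the cell type in a library. Ly6c1 reached 2524 ± 274 CPM (SD, n = 4) in endothelial-like cells against 169.5 ± 105.5 in mural-like and 10.8 ± 5.38 in podocyte-like cells. Mural-like cells carried Ren1, the renin gene (GRCm38 chromosome 1, 133350510 to 133360325), at 6278 ± 4458, smooth muscle actin Acta2 at 4613 ± 777, and the mesangial markers Itga8 at 222 ± 101 and Pdgfrb at 137 ± 64.1 CPM, all in 1 cluster. Parietal epithelial-like cells carried Dkk3 at 252 ± 31.3, Pax8 at 103 ± 63.5 and Cldn1 at 89.8 ± 33.2 CPM, whereas Pax2 stood at 2.02 ± 4.04. Podocyte markers took 1.48% of the UMIs of parietal epithelial-like cells (1.36% to 1.70% in 4 libraries), between the 2.43% ± 0.158 of podocyte-like and the 0.472% ± 0.0547 of endothelial-like cells. Tubular-like cells carried distal markers, with Fxyd2 at 7789 ± 634, the sodium-chloride cotransporter Slc12a3 at 3331 ± 269.7 and uromodulin (Umod) at 2261 ± 326 CPM. Slc34a1, the phosphate transporter of the proximal tubule, stood at 0.460 ± 0.920 CPM in the same cells, below the 1.40 that 3 UMIs make there. The tubular-like cells also had the highest median mitochondrial share, 14.1%, against 4.27% in podocyte-like cells. Cells with marker transcripts of 2 types made up 2.27% of all kept cells, 8.59% of endothelial-like, 14.0% of mural-like and 10.1% of tubular-like cells. This rule did not count podocyte markers in parietal epithelial-like cells, nor parietal epithelial markers in any cell. Mixtures of podocytes and parietal epithelial cells were therefore not seen by it.

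The next comparisons asked which genes each cell type carried, beyond those that shaped the clusters. Of 282 genes in 11 lists that were kept out of the clustering, 208 could be tested among 7559 genes, each type against the mean of the other 4. Log2 folds are over that mean, and every gene named with a log2 fold above 0 was higher in 4 of 4 libraries except Ier3 in tubular-like cells (3 of 4). List counts were the same when adjusted over the list alone unless a second count is given.

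Podocyte-like cells held more of the transcripts of slit diaphragm and foot process genes and of genes mutated in inherited nephrotic syndrome. Enpep, which encodes aminopeptidase A (chromosome 3, 129269175 to 129332720), reached 1338 ± 137 CPM (SD, n = 4) in podocyte-like cells against 914 ± 92.1 in parietal epithelial-like, 252 ± 58.9 in endothelial-like, 216 ± 75.4 in mural-like and 118 ± 27.7 in tubular-like cells. Within endothelial-like cells Enpep was among the 10 leading genes of subcluster 1, where 77.1% of cells carried markers of 2 types. Its log2 fold was 2.19 (SE 0.0890; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.43e-35). Vegfa, the growth factor on which glomerular endothelium depends, reached 1779 ± 84.9 CPM and 1064 ± 113 in parietal epithelial-like cells (SE of its log2 fold 0.0839, adjusted p = 1.19e-33), and Sema3g, a secreted semaphorin, 1446 ± 134 and 856 ± 181 (log2 fold 2.23, SE 0.0853). Of the 31 inherited nephrotic syndrome genes tested, 23 rose and 2 fell (23 and 3 adjusted over the list alone; camera, adjusted p = 2.68e-08, and adjusted p = 0.0399 with an estimated correlation). Among them were Ptpro (2.05), Daam2 (1.97), Col4a3 (1.89), Magi2 (1.87) and Plce1 (1.86), while Sgpl1 fell by 0.78 on the log2 scale and Osgep stood at -0.53 (lower in 2 of 4 libraries). Of 20 slit diaphragm and foot process genes, 17 rose and 0 fell (adjusted p = 1.75e-09, and adjusted p = 0.0282 with an estimated correlation), led by dendrin (Ddn, 2.43), nestin (Nes, 1.89) and podoplanin (Pdpn, 513 ± 57.7 CPM). The complement regulators Cd55 (2.36) and Cd59a (1.90) were among 5 complement and coagulation genes that rose, 3 of 12 fell, and that list as a whole did not stand apart (adjusted p = 0.318).

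In podocyte-like cells 11 of 18 arterial genes (adjusted p = 1.45e-07, and adjusted p = 0.0465 with an estimated correlation) and 11 of 16 fenestrated endothelial genes (adjusted p = 2.68e-08, and adjusted p = 0.0110 with an estimated correlation) fell. Cxcl12 (1.13) and Ehd4 (1.11) were the single members that rose. Tinagl1, a matrix protein of vessels, stood at a log2 fold of -6.30, caveolin Cav1 at -5.92 and Fbln5 at -5.78. Of 20 contractile genes 12 fell and 5 rose (adjusted p = 0.00509, and adjusted p = 0.142 with an estimated correlation). Of 23 vascular growth factor and receptor genes 10 fell, Pdgfa by 5.65 on the log2 scale, and 8 rose, among them Robo2 (2.18) and Bmp7 (1.94; adjusted p = 0.0314, and adjusted p = 0.152 with an estimated correlation). Matrix genes went both ways (9 of 17 higher, 6 lower; median 0.48, mean -1.43; adjusted p = 0.882), with Npnt at 1.91. Renin-angiotensin and vasoactive genes did too (5 of 11 higher, 4 lower, camera's adjusted p = 0.736), with the natriuretic peptide receptor Npr3 at 1.99. Immediate-early genes, which respond within minutes to a stimulus, were higher in 21 of 32 and lower in 5 (median 0.46; adjusted p = 0.000377, and adjusted p = 0.0898 with an estimated correlation). Egr2 stood at 1.87, with 58.1 CPM in podocyte-like and 79.9 in parietal epithelial-like cells. Heat-shock genes were higher in 12 of 17 and lower in 1 (13 and 1 adjusted over the list alone; adjusted p = 0.0136, and adjusted p = 0.303 with an estimated correlation), the lower one being Bag3 at -1.30. Over all lists 102 of the 208 genes rose and 62 fell (103 and 63 adjusted over the list alone), and DESeq2 gave 85 and 82. With a mitochondrial limit of 10% the count of rises was 67.

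**Figure D2:**
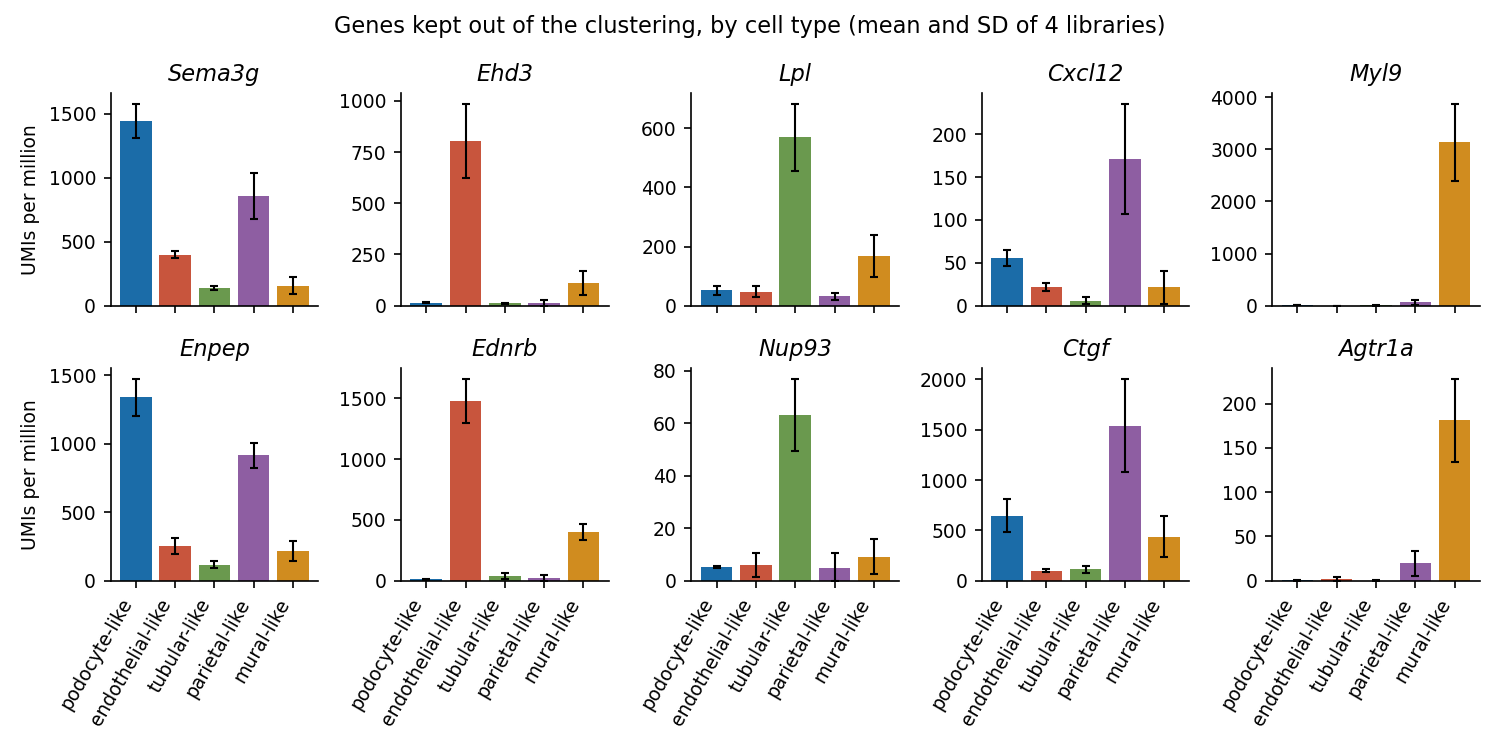
CPM of 10 genes kept out of the clustering in 5 cell types, as bars from 0 at the mean of 4 Drop-seq libraries with error bars of 1 SD. Each pair of panels shows a cell type's genes, from Sema3g and Enpep in podocyte-like cells (1446 and 1338) to Myl9 and Agtr1a in mural-like cells (3134 and 181).

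Endothelial-like cells carried the receptors for vascular growth factors and the genes of fenestrated and arterial endothelium. The VEGF receptors Flt1 and Kdr reached 702 ± 105 and 537 ± 88.0 CPM (SD, n = 4), against 49.9 ± 50.8 and 54.0 ± 39.8 in mural-like and 6.31 ± 2.40 and 4.62 ± 2.44 in podocyte-like cells, with log2 folds of 5.88 (SE 0.167) and 5.92 (SE 0.182). Ehd3, a membrane-trafficking gene of glomerular endothelium (chromosome 17, 73804134 to 73832094), reached 805 ± 181 and 111 ± 60.6 in mural-like cells (log2 fold 5.12, SE 0.145; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.02e-46). The endothelin receptor gene Ednrb stood at 1478 ± 184 and at 399.6 ± 64.3 in mural-like cells (log2 fold 5.12, SE 0.121). Of 16 fenestrated endothelial genes 15 rose, among them Tspan7 (5.10), the fatty acid transporter Cd36 (5.22) and the water channel Aqp1 (5.21), and Lpl fell by 1.32 on the log2 scale (camera, adjusted p = 4e-11, and adjusted p = 0.00506 with an estimated correlation). Of 18 arterial and flow-responsive genes 17 rose and 0 fell (adjusted p = 4e-11, and adjusted p = 0.0260 with an estimated correlation), with thrombomodulin (Thbd) at 5.96, fibulin Fbln2 at 5.40 and the nitric oxide synthase Nos3 at 5.23. Of 23 vascular growth factor and receptor genes 12 rose and 5 fell (adjusted p = 0.00333, and adjusted p = 0.0737 with an estimated correlation), Vegfb by 3.07 on the log2 scale. Tie1, Tek and Sox17, at 171 ± 18.9, 279.7 ± 43.5 and 392 ± 61.4 CPM in endothelial-like cells, had 0 UMIs in parietal epithelial-like cells, which allowed up to 7.80 CPM there (3 UMIs over 4 libraries), so no fold is given.

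Nephrotic syndrome, contractile, and renin-angiotensin and vasoactive genes were lower in endothelial-like cells at the preset correlation only. Of 31 inherited nephrotic syndrome genes 15 fell and 3 rose (adjusted p = 0.0303, and adjusted p = 0.323 with an estimated correlation). Of 20 contractile genes 10 fell and 4 rose (camera, adjusted p = 0.00183, and adjusted p = 0.107 with an estimated correlation). Of 11 renin-angiotensin and vasoactive genes 5 fell and 2 rose (adjusted p = 0.0191, and adjusted p = 0.0700 with an estimated correlation). Slit diaphragm (3 of 20 higher, 8 lower; adjusted p = 0.109), matrix (7 of 17 higher, 5 lower; adjusted p = 0.781) and heat-shock genes (9 of 17 higher, 3 lower; adjusted p = 0.0687) did not stand apart. Immediate-early genes were higher in 13 of 32 and lower in 11 (13 and 12 adjusted over the list alone), with a median of 0.03, a mean of 0.18 and a test direction below 0 (adjusted p = 0.675). Complement and coagulation genes had a median of -0.01, a mean of 0.29 and a test direction above 0 (5 of 12 higher, 4 lower, 5 and 5 adjusted over the list alone; adjusted p = 0.839 with an estimated correlation). Over all lists 86 genes rose and 64 fell (86 and 66 adjusted over the list alone); with at least 500 genes per cell 37 fell. Podocyte markers took 0.472% ± 0.0547 of the UMIs of these cells.

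Mural-like cells were set apart by contractile genes. Myl9, a regulatory light chain of myosin, reached 3134 ± 741 CPM (SD, n = 4) in mural-like cells, 66.8 ± 52.5 in parietal epithelial-like and 7.92 ± 1.84 in podocyte-like cells, a log2 fold of 7.95 (SE 0.152; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.42e-57). Tropomyosin Tpm2 reached 2229 ± 892 (log2 fold 8.55, SE 0.184) and filamin A (Flna) 418 ± 221 (4.80). The angiotensin II receptor gene Agtr1a stood at 181 ± 47.3 CPM against 19.7 ± 13.8 in parietal epithelial-like cells (log2 fold 6.38, SE 0.466). Of 20 contractile genes 18 rose and 0 fell (camera, adjusted p = 5.4e-18, and adjusted p = 0.00506 with an estimated correlation). Endothelial lists were higher as well, with 10 of 16 fenestrated genes (11 adjusted over the list alone; adjusted p = 0.000249, and adjusted p = 0.0451 with an estimated correlation) and 9 of 18 arterial genes, among them the gap junction gene Gja4 (4.87, at 221 ± 62.7 CPM against 156 ± 50.7 in endothelial-like cells; adjusted p = 0.00882, and adjusted p = 0.256 with an estimated correlation). Endothelial markers took 0.0747% ± 0.0269 of the UMIs of mural-like cells and 0.00453% ± 0.00204 of those of podocyte-like cells, and 14.0% of mural-like cells carried markers of 2 types. Of 12 complement and coagulation genes 5 rose, among them the C1 inhibitor Serping1 (5.38), and 3 fell (6 and 4 adjusted over the list alone; adjusted p = 0.0359, and adjusted p = 0.0821 with an estimated correlation).

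Of 11 renin-angiotensin and vasoactive genes 5 rose and 3 fell in mural-like cells, with a median of 0.15 (camera, adjusted p = 0.0416, and adjusted p = 0.0923 with an estimated correlation). The neprilysin gene Mme fell by 2.38 on the log2 scale. Of 20 slit diaphragm genes 11 fell, ezrin (Ezr) by 2.07 on the log2 scale, and 3 rose (12 and 3 adjusted over the list alone; adjusted p = 0.0372, and adjusted p = 0.345 with an estimated correlation). The nuclear receptor gene Nr4a2 reached 797 ± 180.3 CPM, whereas immediate-early genes as a list split into 11 higher and 11 lower of 32 (12 and 13 adjusted over the list alone; adjusted p = 0.115). Vascular growth factor (9 of 23 higher, 3 lower, 11 and 5 adjusted over the list alone; adjusted p = 0.0687), matrix (8 of 17 higher, 4 lower, 8 and 5 adjusted over the list alone; adjusted p = 0.115), nephrotic syndrome (3 of 31 higher, 6 lower, 3 and 7 adjusted over the list alone; adjusted p = 0.271) and heat-shock genes (1 of 17 higher, 5 lower; adjusted p = 0.278) did not stand apart. Over all lists 79 genes rose and 44 fell (83 and 54 adjusted over the list alone). The count of falls was between 26 and 28 with at least 500 genes per cell, a mitochondrial limit of 10% or another resolution, and 71 against all other cells summed; 3 of the 6 lists past the threshold were left without replicate 1, and 3 without replicate 2.

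Parietal epithelial-like cells carried chemokine and immediate-early transcripts together with podocyte transcripts. Cxcl12, a chemokine (chromosome 6, 117168535 to 117181367), reached 171 ± 64.5 CPM (SD, n = 4) against 55.7 ± 9.82 in podocyte-like and 21.7 ± 4.38 in endothelial-like cells, a log2 fold of 3.10 (SE 0.295; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.28e-14), and its scavenger receptor gene Ackr3 146 ± 37.0 (2.57). Ctgf, a matricellular growth factor, reached 1542 ± 466 (log2 fold 2.58, SE 0.106) and Cyr61 1893 ± 567 (2.11, SE 0.107), against 644 ± 164 and 886 ± 162 in podocyte-like cells. Of 32 immediate-early genes 20 rose and 3 fell (23 and 4 adjusted over the list alone; camera, adjusted p = 4.66e-08, and adjusted p = 0.0282 with an estimated correlation). Of 12 complement and coagulation genes 8 rose and 0 fell, with tissue factor (F3) at 2.37 (9 and 2 adjusted over the list alone; adjusted p = 0.00729, and adjusted p = 0.0446 with an estimated correlation). Of 17 matrix genes 10 rose and 0 fell, with Sparc at 1.64 (adjusted p = 0.000459, and adjusted p = 0.0970 with an estimated correlation). Of 20 slit diaphragm genes 14 rose and 1 fell, with vimentin (Vim, 1.72) and dystroglycan (Dag1, 1.60; 15 and 1 adjusted over the list alone; adjusted p = 1.45e-07, and adjusted p = 0.0451 with an estimated correlation). Of 31 nephrotic syndrome genes 16 rose and 1 fell (adjusted p = 6.7e-06, and adjusted p = 0.0700 with an estimated correlation). Podocyte markers took 1.48% of the UMIs of these cells (mean of 4 libraries), and Col4a3 (log2 fold 1.75) stood at 1217 ± 369.7 CPM in them and at 1244 ± 135 in podocyte-like cells.

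Fenestrated endothelial genes were lower in parietal epithelial-like cells (0 of 16 higher, 7 lower, 1 and 7 adjusted over the list alone; adjusted p = 5.95e-07, and adjusted p = 0.0173 with an estimated correlation). Arterial genes went the same way in the test (3 of 18 higher, 4 lower, 3 and 6 adjusted over the list alone; adjusted p = 0.00686, and adjusted p = 0.239 with an estimated correlation). Igfbp5 fell by 3.92 on the log2 scale. Renin-angiotensin and vasoactive genes were higher in 7 of 11 and lower in 0 (camera, adjusted p = 0.0354, and adjusted p = 0.0839 with an estimated correlation). Among the higher ones was the prostacyclin synthase gene Ptgis (3.91). Ptgis stood at 99.5 ± 52.8 CPM, with 1 library at 178.4 and the next at 79.26, and at 169 ± 75.5 in mural-like cells. Contractile genes were higher in 10 of 20, among them smoothelin (Smtn, 1.93), and lower in 1 (11 and 3 adjusted over the list alone; adjusted p = 0.0477, and adjusted p = 0.307 with an estimated correlation). Vascular growth factor (9 of 23 higher, 7 lower; adjusted p = 0.169) and heat-shock genes (1 of 17 higher, 4 lower, 1 and 5 adjusted over the list alone; adjusted p = 0.174) did not stand apart. Over all lists 93 genes rose and 26 fell (99 and 34 adjusted over the list alone). Against all other cells summed, which are mostly podocyte-like, 28 rose and 45 fell and the call of Col4a3 was lost; the count of rises was 48 with a mitochondrial limit of 10%.

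In tubular-like cells 10 of 11 lists were lower at the preset correlation and 5 with an estimated one. Immediate-early genes fell in 28 of 32 and rose in 2, Gadd45g (1.30) and Ier3 (0.26), with a list median of -1.16 (camera, adjusted p = 3.07e-10, and adjusted p = 0.0173 with an estimated correlation). Gadd45g stood at 189 CPM in tubular-like and 360 in mural-like cells. Lpl, which encodes lipoprotein lipase, reached 569.8 ± 114 CPM (SD, n = 4) in tubular-like cells against 168 ± 70.0 in mural-like and 47.1 ± 18.1 in endothelial-like cells, a log2 fold of 3.49 (SE 0.131; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.97e-38). The laminin chain Lamb1 reached 101 ± 7.83 (log2 fold 3.79, SE 0.271), the nucleoporin gene Nup93 63.3 ± 13.8 (3.58, SE 0.323) and Vegfb 112 ± 11.2 (3.11, SE 0.226). The cyclooxygenase gene Ptgs1 stood at 31.6 ± 14.3 CPM (2.57, SE 0.385) and at 26.7 ± 5.85 in endothelial-like cells. Cnn3 (1.47) was also higher. Cav2 exceeded the mean of the other types (1.95), at 105 ± 35.8 CPM, but reached 155 ± 18.4 in endothelial-like cells. The transcription factor gene Meis2 fell by 4.41 on the log2 scale. Falls made up 15 of 20 contractile genes, with 1 rise (16 and 1 adjusted over the list alone; adjusted p = 1.99e-07, and adjusted p = 0.0282 with an estimated correlation), 9 of 12 complement genes, with 0 rises (adjusted p = 4.66e-05, and adjusted p = 0.0110 with an estimated correlation), and 14 of 23 vascular growth factor genes, with 2 rises (adjusted p = 0.000459, and adjusted p = 0.0451 with an estimated correlation). Of 11 renin-angiotensin and vasoactive genes 5 fell and 1 rose (camera, adjusted p = 0.00978, and adjusted p = 0.0476 with an estimated correlation).

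The call of the other falling lists in tubular-like cells was lost with an estimated correlation. These were slit diaphragm genes (16 of 20 lower, 2 higher; adjusted p = 1.42e-05, and adjusted p = 0.0737 with an estimated correlation), nephrotic syndrome genes (22 of 31 lower, 3 higher; adjusted p = 4.95e-05, and adjusted p = 0.0839 with an estimated correlation) and matrix genes (15 of 17 lower, 1 higher; adjusted p = 8.27e-05, and adjusted p = 0.0751 with an estimated correlation). Arterial genes (11 of 18 lower, 0 higher; adjusted p = 0.000377, and adjusted p = 0.126 with an estimated correlation) and fenestrated genes (6 of 16 lower, 3 higher; adjusted p = 0.00841, and adjusted p = 0.101 with an estimated correlation) followed. Heat-shock genes went both ways (3 of 17 higher, 7 lower; adjusted p = 0.228), with the mitochondrial chaperones Hspd1 at 0.83 and Hspe1 at 0.80. These calls were lost with a mitochondrial limit of 10%, and Hspe1 stood at 529 ± 72.1 CPM in tubular-like and 621 ± 179 in podocyte-like cells. Over all lists 18 genes rose and 140 fell (18 and 142 adjusted over the list alone). With a mitochondrial limit of 10% these counts were 7 and 61, and the tubular-like share was 1.13%.

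Endothelial-like cells were divided further, to ask whether subsets differed in arterial and fenestrated genes. Subcluster 2 (634 cells) held more transcripts of arterial genes, and subcluster 3 (1013 cells) more of the VEGF receptor gene Kdr and the plasminogen activator gene Plat. Mgp, an inhibitor of calcification made in arteries (chromosome 6, 136872435 to 136875823), stood at 624 ± 277 CPM (SD, n = 4) in subcluster 2 and 42.0 ± 35.9 in subcluster 3, a log2 difference of 3.94 (SE 0.314; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.79e-14; higher in 4 of 4 libraries). The elastic fibre gene Fbln5 (chromosome 12, 101746565 to 101819055) differed by 3.72 (461 ± 169 and 34.6 ± 19.2), Fbln2 by 3.44, the Notch ligand Jag1 by 3.22, Vim by 2.79, Gja4 by 2.43, endothelin Edn1 by 2.06 and Npnt by 1.72. In the other direction, higher in subcluster 3 in 4 of 4 libraries, the log2 difference was -2.27 for Plat (717 ± 179 and 3446 ± 449 CPM), -2.20 for Ehd3 (282 ± 26.8 and 1339 ± 293), -1.99 for Hsph1, -1.93 for Kdr, -1.63 for Ednrb, -1.51 for Plpp3, -1.45 for Igfbp5 and -1.35 for Nostrin.

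Of 16 arterial genes 11 were higher in subcluster 2 and 1, Dll4 (-0.95), in subcluster 3 (12 and 2 adjusted over the list alone; camera, adjusted p = 1.29e-06, and adjusted p = 0.0139 with an estimated correlation). Of 15 heat-shock genes 0 were higher in subcluster 2 and 9 in subcluster 3 (adjusted p = 0.000104, and adjusted p = 0.310 with an estimated correlation). Of 9 matrix genes 3 were higher in subcluster 2 and 0 in subcluster 3, with a median of -0.09 and a test direction above 0 (adjusted p = 0.285). Fenestrated genes split into 3 and 5 of 12 (3 and 6 adjusted over the list alone; adjusted p = 0.0367, and adjusted p = 0.431 with an estimated correlation), with Aqp1 (1.18) and Ehd4 (0.89) higher in subcluster 2 in 4 of 4 libraries and Cav1 (0.76) in 3 of 4. Vascular growth factor genes split into 2 and 5 of 12 (2 and 7 adjusted over the list alone; adjusted p = 0.0471, and adjusted p = 0.252 with an estimated correlation), and immediate-early genes into 4 and 6 of 29 (4 and 7 adjusted over the list alone; adjusted p = 0.526). Over all lists 23 of 138 genes were higher in subcluster 2 and 27 in subcluster 3; at resolution 1.0 the first count was 13 and the call of Mgp was lost. Subcluster 1 (192 cells) was led by podocyte genes, with podocyte markers at 1.78% ± 0.195 of UMIs (SD, n = 4) against 0.175% ± 0.0169 in subclusters 2 and 3 together. Subcluster 1 shared the fit of the subclusters but was not compared with the others. Its cells stayed among the endothelial-like cells in the shares and in the comparisons with other cell types.

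**Figure D3:**
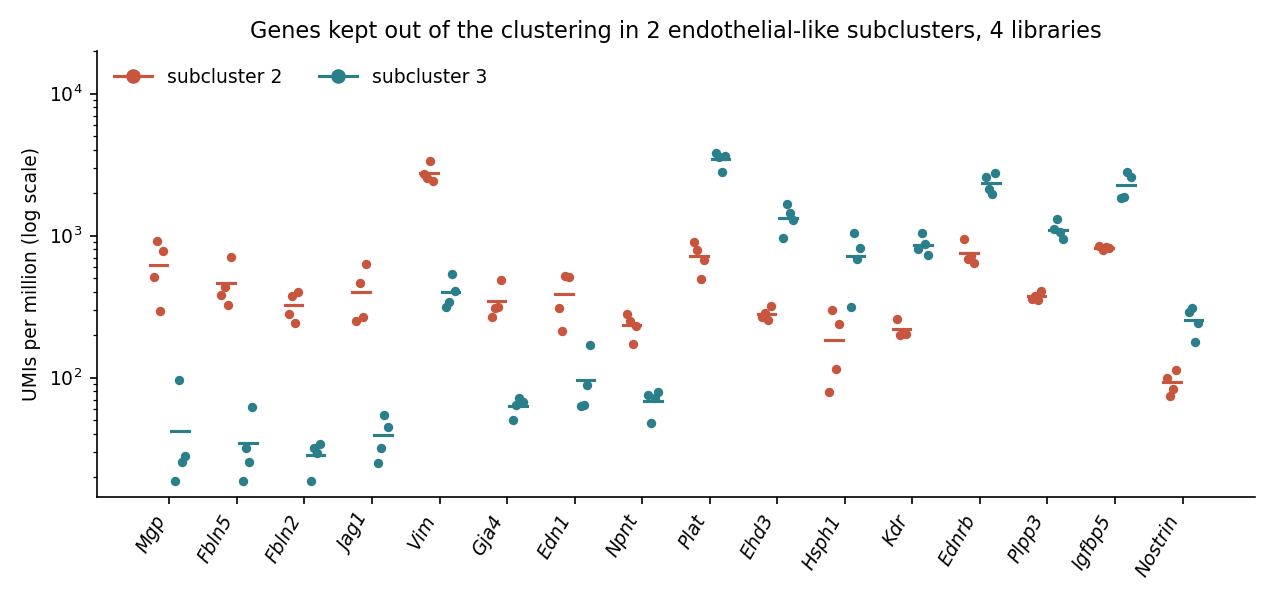
CPM (log axis) of 16 genes kept out of the clustering in endothelial-like subclusters 2 and 3, 1 point per Drop-seq library and a line at the mean of 4. The first 8 genes, from Mgp to Npnt, lie higher in subcluster 2 in every library, and the last 8, from Plat to Nostrin, in subcluster 3.

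The bulk libraries were compared to ask how dissociated, fixed cells differed from whole live glomeruli. Immediate-early genes were far more abundant in the dissociated cells, and transcripts of mesangial cells and of the proximal tubule were far less abundant. The libraries also differed in sorting and in the RNA put in. With 1 library each there was no replicate, so no test was run, intervals cover counting error only, and the ratios compare these libraries, not the conditions. Egr2 rose from 0.475 CPM (95% exact Poisson interval 0.266 to 0.784) to 120.4 (116 to 125), a log2 ratio of 7.78, and Atf3, a stress-induced transcription factor, from 50.3 (47.9 to 52.9) to 4091 (4064 to 4118), a log2 ratio of 6.34. Itga8, the integrin chain of mesangial cells (chromosome 2, 12106632 to 12301922), stood at 1189 CPM (1177 to 1201) in whole glomeruli and 13.5 (at most 15.1) in dissociated cells, a log2 ratio of -6.45. Of 12692 genes with at least 100 counts, 1347 were at least 2-fold higher and 2423 at least 2-fold lower in dissociated cells, 236 and 1172 of them at least 4-fold. Scaled by library total instead of by TMM, the median ratio of all genes moved from -0.02 to -0.32 and the counts were 759 higher and 3180 lower.

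Immediate-early genes had a median log2 ratio of 2.85, above all of 10000 random lists matched on expression (percentile 100), and 27 of 34 were at least 2-fold higher and 0 lower, with Maff at 5.89 and Nr4a3 at 5.62. Heat-shock genes had a median of 1.15 (percentile 100; 11 of 17 at least 2-fold higher, 0 lower), with Dnajb4 at 3.48, Hsp90aa1 at 2.07, and Hspa1b at 1.86, whose reads a near-identical copy could share. Podocyte markers had a median of 1.15 (percentile 97.2; 9 of 11 higher, 0 lower), with Cdkn1c at 1.84. Immune markers had a median of 1.65 (percentile 100; 7 of 8 higher, 0 lower), with Lyz2 at 1.83. Slit diaphragm genes had a median of 0.55, which was 0.25 by library total (percentile 75.4; 5 of 21 higher, 1 lower), with Vim at 2.39 and Ezr at 2.05. Nephrotic syndrome genes had a median of 0.26, which was -0.04 when scaled by library total (percentile 51.0; 5 of 46 higher, 3 lower), with Plce1 at 1.44, Kank4 at -4.10 and Trpc6 at -3.33. Parietal epithelial markers had a median of 0.15, which was -0.15 by library total (percentile 80.8; 0 of 4 higher, 1 lower). Outside the lists Mlf1 (7.43), Rbpjl (6.61), Ifrd1 (5.86) and Lag3 (5.67) rose most among genes with more than 3 reads in each library.

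Mesangial markers fell as a group, with a median of -4.83, below all random lists (percentile 0), and 9 of 9 at least 2-fold lower. Ptn stood at -6.77, Sfrp2 at -5.86 and Gata3 at -5.09. Smooth muscle and renin markers had a median of -0.19, which was -0.50 by library total (percentile 21.6; 0 of 7 higher, 3 lower), with Notch3 at -3.01 and Myh11 at -0.19. Fenestrated endothelial genes had a median of -1.95 (percentile 0; 0 of 19 higher, 18 lower), with Gata5 at -4.91 and Ehd3 at -3.60. Arterial genes stood at -1.39 (percentile 0; 0 of 22 higher, 15 lower), with the connexin Gja5 at -5.58, and endothelial markers at -1.51 (percentile 0; 0 of 10 higher, 8 lower), with Ptprb at -2.73. Vascular growth factor genes had a median of -1.78 (percentile 0; 4 of 30 higher, 18 lower), with Pdgfra at -6.91, Angpt2 at -4.66 and Igfbp5 at -4.52. Renin-angiotensin and vasoactive genes had a median of -1.69 (percentile 0, with 2 of 19 higher and 11 lower), with the guanylate cyclase subunit Gucy1a3 at -5.49 and Agtr1a at -5.04. Matrix genes had a median of -1.23 (percentile 0; 1 of 26 higher, 14 lower), with Postn at -6.12, Bgn at -4.64 and Col4a2 at -3.80. Complement and coagulation genes had a median of -0.99 (percentile 0.01; 4 of 17 higher, 8 lower), with F3 at 3.12. Contractile genes had a median of -0.40, which was -0.70 by library total (percentile 0.180; 3 of 19 higher, 8 lower), with Myl9 at -2.94 and Csrp2 at 2.36. Red blood cell markers had a median of -1.19 (percentile 8.86; 0 of 5 higher, 3 lower). With the trend on transcript length and GC content removed, the median was -0.41 (SE 0.868, from resampling genes) for complement and coagulation genes. The medians were -0.73 for matrix, -1.09 for renin-angiotensin and vasoactive, 1.07 for slit diaphragm and 0.63 for nephrotic syndrome genes. They were 0.42 for parietal epithelial and -0.20 for tubular markers (-0.08 without the proximal ones), and those of the other lists moved by less than 1.5 times.

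Tubular markers had a median of -0.60, which was -0.90 by library total (percentile 0.805; 0 of 15 higher, 7 lower), and, split after their values were seen, 6 proximal tubule markers had a median of -6.51 and the other 9 a median of -0.22. Slc34a1 (chromosome 13, 55398187 to 55415592) fell from 307 CPM to 1.45 (log2 ratio -7.65), and the proximal tubule genes Acsm2 (-8.40) and Pck1 (-7.86) were among the largest falls. The transporter genes Slc13a3 and Slco1a1, with 0 reads in the dissociated library, were at least 224-fold and 165-fold lower (against 3 reads per library). No list gene had 0 reads in either library.

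**Figure D4:**
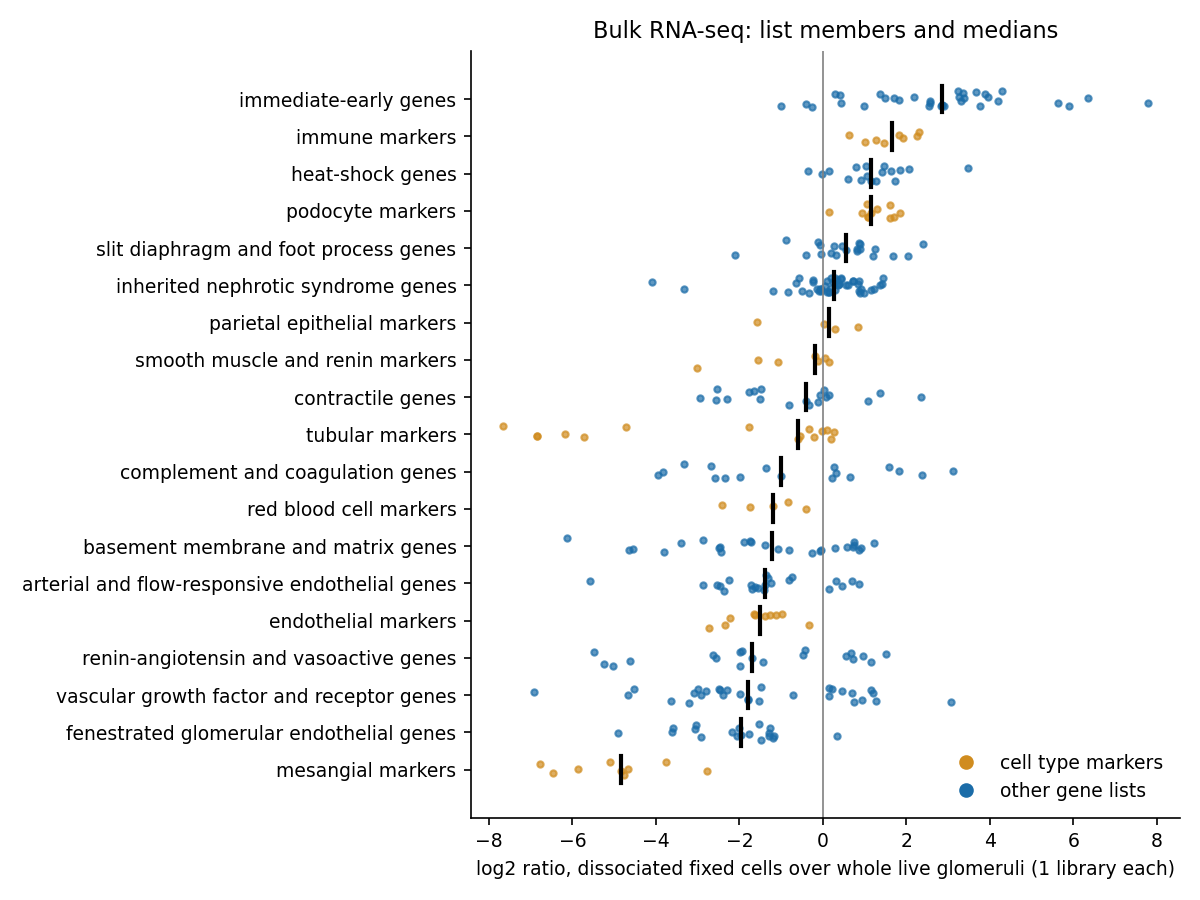
Log2 ratio of dissociated fixed cells over whole live glomeruli in bulk RNA-seq (1 library each) for the members of 19 gene lists, as points, with a black bar at each list's median. Immediate-early genes lie farthest to the right (median 2.85) and mesangial markers farthest to the left (median -4.83).

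The Drop-seq libraries, summed over cells, were set against both bulk libraries to ask how close single cells came to each. Across genes, which are not independent replicates, the Spearman correlation was 0.749 ± 0.0178 (SD, n = 4) with the dissociated bulk library and 0.561 ± 0.0231 with the whole one, and each Drop-seq library lay closer to the dissociated one. Between Drop-seq libraries it was 0.962 to 0.979. Fos (chromosome 12, 85473890 to 85477273), chosen after its values were seen, stood, scaled by library total and not by TMM, at 8655 ± 497 CPM in Drop-seq, 10775 in dissociated bulk and 1046 in whole bulk. Itga8 stood at 5.45 ± 3.05, 12.1 and 1320.5 CPM in the same order and scaling. For lists, the median log2 ratio of Drop-seq to bulk was taken minus the median of all genes compared. A value above 0 therefore means a list above the median gene, not a higher CPM in Drop-seq. Over immediate-early genes this relative median was 3.07 ± 0.170 to whole and 0.05 ± 0.119 to dissociated bulk (31 and 32 genes). Over 9 mesangial markers it was -4.40 ± 0.750 to whole bulk. Only 6 of them had enough reads in dissociated bulk, where it was 0.04 ± 0.579, so the gene sets differ. Podocyte markers lay at 0.27 ± 0.0986 and -0.80 ± 0.0834, endothelial markers at -2.52 ± 0.573 and -0.69 ± 0.642, and heat-shock genes at 2.18 ± 0.569 and 1.17 ± 0.463. Drop-seq counts come from transcript ends and bulk reads from whole transcripts, so levels set across the 2 assays differ in more than the cells.

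**Figure D5:**
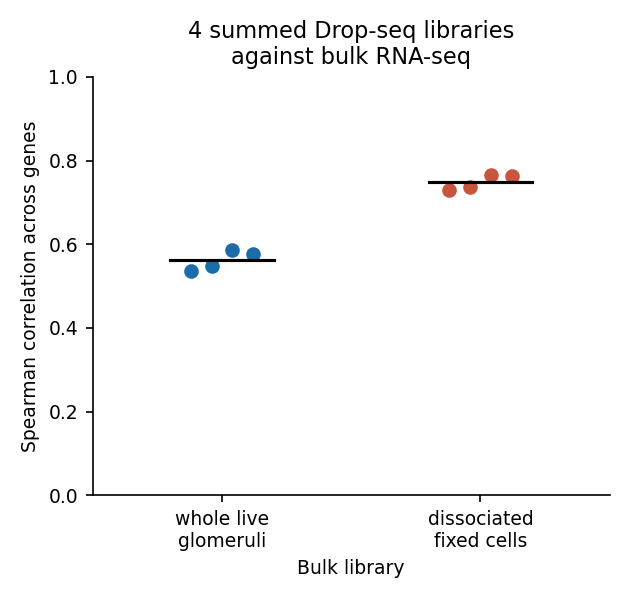
Spearman correlation across genes (axis from 0 to 1) of each of 4 summed Drop-seq libraries with each bulk library, with a line at the mean of 4. The points lie between 0.537 and 0.585 for whole live glomeruli and between 0.730 and 0.766 for dissociated fixed cells.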

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

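Of the tests in this part, those on transcript length and GC content and on barcodes with RNA of 2 cells were chosen before the results were seen, and all the others only after. The cell type groups were compared with random regroupings of the same sums. The real grouping gave 164 held-out genes past the threshold in podocyte-like (highest other 29) and 150 in endothelial-like cells (highest other 12). It gave 123 in mural-like (highest other 6), 119 in parietal epithelial-like (highest other 33) and 158 in tubular-like cells (highest other 6). Only 1 of 40 splits, the real one, gave as many. The groups came from clustering these same cells, and genes of 1 cell type vary together, so the real grouping was set to lead. The comparison therefore cannot exclude chance. For endothelial subclusters 2 and 3 (50, highest other 0; 1 of 8) the splits are too few for a share under 0.05.

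Mesangial markers were lower in the dissociated bulk library, with log2 ratios from -6.77 to -2.78. A single scaling factor could not explain this, because podocyte and mesangial markers differed by 5.98 (SE 0.522) on the log2 scale. The SEs in this part come from resampling the genes of a list and do not measure spread between libraries. Transcript length and GC content were excluded too, since the mesangial median stayed at -4.85 (SE 0.496) with their trend removed. A loss of mesangial cells during dissociation or sorting is possible but was not tested, because that 9 of 9 markers were at least 2-fold lower only restates the pattern, and the cause stays open. Counting mesangial cells in tissue before and after dissociation and after sorting would test this.

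Immediate-early genes rose in the dissociated bulk library. Their median exceeded the highest marker median, that of 8 immune markers, by 1.201 (SE 0.420, over genes). In these 2 libraries this argues against a larger share of a listed cell type as the whole cause. With 1 library each, such a share is not excluded. With the trend on length and GC content removed the median was 3.09 (SE 0.291). The rise may come from dissociation, fixation, sorting or the time they took, and these cannot be told apart, since 0 libraries were dissociated and not fixed. A library of dissociated, unfixed cells and one made with a transcription inhibitor would test this.

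Endothelial-like subcluster 1 carried podocyte transcripts. Free RNA is excluded as the cause, because their share of UMIs was 10.2 (SD 1.19, n = 4) times that in subclusters 2 and 3, which shared the same droplets' background. Barcodes with RNA of 2 cells may explain it: the fraction of the podocyte level and the fraction of the endothelial level added up to 1.03 (SD 0.0371), and the median UMI count was 1301 against 627 in the other subclusters. Mixing cells of 2 species in the same droplet run would test this.

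Among 186 groups of 4 library values, 12 held a value far from the other 3, and about 1 in 20 groups would by chance. The tubular-like share was 10.93% in replicate 2, next 5.66%. Lowest values stood apart in podocyte-like cells for Npnt (980.2 CPM, next 1086), Col4a3 (1043, next 1284) and Epn3 (62.9, next 72.8), in endothelial-like cells for Tspan7 (285.3, next 375.9) and in parietal epithelial-like cells for Igfbp5 (8.073, next 11.3). Highest values stood apart in parietal epithelial-like cells for Ptgis (178.4 CPM, next 79.26), Egr2 (135.9, next 67.83) and Smtn (169.5, next 147.2), in tubular-like cells for Lpl (739.2, next 533), in subcluster 3 for Mgp (95.54, next 28.3) and in mural-like cells for Egr2 (10.18, next 0). Of the barcodes left out for their mitochondrial share, 92.81% were tubular-like. The barcodes left out held 1996 hemoglobin UMIs, 1474 and 519 of them in 2 barcodes.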

How the results depend on the processing

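All alternatives here were set before the results were seen except 2 for doublets and the runs without 1 library for lists and for the correlation. Of the summaries 412 stayed and 34 moved. A share or correlation counted as moved at a change of at least 1 SD of the 4 libraries, and a count at a change above 1.5-fold. A bulk list median counted as moved outside its 95% range from resampling genes. The entries with no doublets removed copied the main value. Leaving out 1 of 4 libraries cannot shift a mean by 1 SD, so those shares and correlations could not move either. Of the named genes by cell type, 93 of 121 kept their call in every alternative in which they were tested. A gene that an alternative did not test counted as kept there. The 2 that changed sign did so only against all other cells summed: Crb2 in parietal epithelial-like cells (-0.33) and Ezr in tubular-like cells (-0.47). The cause of these and of the moved values was not tested. From 96.2% to 98.5% of cells kept their type when clustered again.

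With a mitochondrial limit of 10% the shares were 81.6% podocyte-like and 1.13% tubular-like, and the held-out genes were 67 higher in podocyte-like, 27 lower in mural-like, 48 higher in parietal epithelial-like, and 7 higher and 61 lower in tubular-like cells. With at least 500 genes per cell the shares were 4.01% parietal epithelial-like and 0.204% immune-like, and 37 genes were lower in endothelial-like, 28 lower in mural-like and 57 higher in parietal epithelial-like cells, a class of 384 cells there against 335, so it took in cells named otherwise in the report. Without a mitochondrial limit the parietal epithelial-like share was 2.83%, and at resolution 2.0 it was 3.19%, a class that there took in a cluster of 59 cells led by the intercalated cell genes Atp6v1g3, Atp6v0d2, Slc4a9 and Aqp6, with 26 genes lower in mural-like cells. At resolution 0.5 the counts were 28 lower in mural-like and 48 higher in parietal epithelial-like cells, but 128 of the 386 cells of that class came from a cluster led by the collecting duct genes Atp6v1g3, Aqp2 and Hsd11b2, so it is not the class of the report. Against all other cells summed 71 genes were lower in mural-like cells, and 28 were higher and 45 lower in parietal epithelial-like cells. With separate UMIs for clustering and testing 14 genes were lower in parietal epithelial-like cells, a class that had grown to 419 cells.

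With an estimated correlation 4 lists passed in podocyte-like, 2 in endothelial-like, 2 in mural-like, 4 in parietal epithelial-like and 5 in tubular-like cells. Leaving out 1 library gave 3 to 6 lists in mural-like cells. At endothelial resolution 1.0 the genes higher in subcluster 2 were 13 of 96 tested, against 23 of 138, in smaller clusters. At resolution 0.3 subclusters 2 and 3 merged, so there is no value.

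With no replicate block, held-out genes higher and lower were 94 and 60 in podocyte-like, 84 and 61 in endothelial-like, 76 and 38 in mural-like, 86 and 20 in parietal epithelial-like and 17 and 134 in tubular-like cells, and 18 and 22 between the subclusters. The block was the library itself: residuals of sums from the same library had a median correlation of 0.164 (40 pairs) and those from different libraries -0.06 (120 pairs).

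Scaling by RLE moved the all-gene median from 0.02 to -0.10 in podocyte-like cells, and no scaling moved it from -0.05 to -0.35 in tubular-like cells. In bulk, scaling by library total gave 759 genes at least 2-fold higher and a median log2 ratio of -0.042 for inherited nephrotic syndrome genes, and a limit of 500 counts gave 1451 lower. With no filter on genes the correlation was 0.686 with whole and 0.745 with dissociated bulk, a smaller gap than between 0.561 and 0.749, and by Pearson it was 0.583 and 0.774.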

Other observations

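The tests and genes in this part were chosen only after the results were seen. The tubular-like cells came from 2 clusters. Cluster 0 (795 cells) was led by Klk1, Fxyd2, Defb1, S100g, Pvalb, Calb1 and Umod, genes of the distal nephron. Cluster 6 (166 cells) shared S100g, Klk1, Defb1, Calb1 and Atp1b1 with cluster 0 among its 10 leading genes. The others included genes of the collecting duct: Aqp2, the water channel of principal cells, Atp6v1g3, a proton pump subunit of intercalated cells, and Hsd11b2. Immune-like cells were led by the immunoglobulin chain Igkc and the antigen presentation genes Cd74 and H2-Aa.

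Endothelial-like cells held 1473 hemoglobin UMIs, 1455 of them in 5 barcodes and 1151 in 1, and only 11 of 1839 cells had any. The other kept cells held 51. In bulk, ribosomal protein genes had a median log2 ratio of 1.11, with 59 of 82 at least 2-fold higher in the dissociated library and 0 lower, and mitochondrially encoded genes a median of 0.58. Bulk ratios fell with transcript length, from a median of 0.39 in the shortest genes to -0.30 in the longest (Spearman correlation across genes -0.25, with GC content -0.06).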
